A study of Mus musculus with 24 samples.

How the data were processed

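Input and m6A immunoprecipitated (IP) liver RNA of 12 mice was sequenced in 24 libraries. Per the labels, libraries were stranded and tagged with unique molecular identifiers. Per the submitters' processing notes, HISAT2, StringTie and DESeq were used, without versions; the genome build, the site caller and site coordinates are not given in the sources used here. The signal values are the authors' mean over the compared libraries of counts divided by DESeq2 size factors. The log2 values in the RNA tables are deposited DESeq2 ratios with their SE, and those in the site tables are the authors' log2 of IP over input between groups with an offset per site. The p-value columns were deposited by the authors with an adjusted p, by the Wald test and the Benjamini-Hochberg method in the RNA tables; an adjusted p of 0 is printed as deposited. Each site count is a number of reads summed by the authors over the libraries of a group, without normalization, per the file headers. No values per library are in the 4 RNA and 4 m6A tables, so the planned edgeR fits gave way to the authors' p, as the design fixed beforehand would have it. The 4 count columns of the knockout age site table could not be matched to a group and are not used here.

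Which group was the numerator is not stated. The signs were settled from the values. The 4 RNA contrasts closed to a median absolute residual of 0.00358 over 10563 genes, against 0.411 with the age tables' signs not alike. Wild-type site sums were shared between tables at 21900 sites for 8 weeks and 22361 for 28 weeks, against 26 to 56 for other pairs of columns. The ratio of input reads correlated with the deposited RNA ratio at a Pearson r of -0.78, -0.60 and -0.78 across 9733, 9661 and 9606 genes, which are not independent replicates. RNA signs were therefore turned, so that positive means higher in the knockout or at 28 weeks, and site signs were kept. The authors' p is the test throughout, with an adjusted p under 0.05 as threshold.

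The interaction of genotype and age was the difference of the log2 ratios at both ages, whose libraries are separate, with a Wald p and Benjamini-Hochberg adjustment. The 27 gene lists, written beforehand, were tested with the preranked camera of limma on the Wald statistic, with a preset correlation of 0.01, for lists with at least 3 tested members; members without an adjusted p enter no count or median of a list. The lists cover lipid, bile acid, xenobiotic, sex-biased, stress, clock, growth and m6A genes, neighbours of Apof and markers of cell types, and lists of Y-linked genes, X-linked genes that escape inactivation and genes that decline after birth were added after the results were seen. For m6A, sites were counted by the authors' adjusted p. Knockout age was recomputed at sites found in 3 tables, with 0.5 added to each count and a Wald test on counting error. One gene's m6A value was that of its site with the smallest p.

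The rule for named genes, fixed beforehand, took Apof and, per RNA comparison, the 6 highest and 6 lowest log2 ratios among genes past the threshold with at least 5 CPM in the higher group. It added up to 2 members with the smallest p of each list with a called gene or a passed test, and 4 in the list with most calls. Its condition that libraries do not overlap could not be checked. For m6A it took the 4 highest and 4 lowest called sites, up to 2 sites of each lipid list and the m6A machinery list, and the sites in Apof. Genes of the rule that did not pass, and sites of lists beyond the examples, are given as counts, and a few results the rule named are not reported here. Ddx3y, Kdm5d, Eif2s3y, Apon, the Xist and Igf2 values and the genes called at both ages were also named after their values were seen, where the rule did not take them.

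Counts simulated at this design were fitted with DESeq2. Interaction was called for 33.3% of genes changed by 1 and 78.1% of those changed by 2 log2 units, 0 with the wrong sign. Simulated sites without spread between animals had 0.0313% of unchanged sites called, and 10.6% with a spread of 10%. Preranked camera called 94 of 100 shifted lists and 0 unshifted ones. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and, for simulated counts, DESeq2 1.42.0.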

Results

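Liver RNA was measured in 12 C57BL/6 mice, in an input library and a library of RNA pulled down with an antibody against N6-methyladenosine (m6A, a methyl mark on messenger RNA) from each, 24 libraries in all. The animals formed 4 groups of 3, ApoF knockout and wild type at 8 and at 28 weeks of age. ApoF is an apolipoprotein made in the liver that circulates on lipoproteins. The depth of a single library is not given. Levels below are group means implied by a table's mean and ratio. Mean normalized counts summed to between 39824285 and 41989205 per RNA table, and reads at the listed m6A sites to between 72868528 and 90420947 per group and library type. Gene values are log2 ratios ± SE from 3 animals per group, positive where the knockout, or the 28-week group, was higher.

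Apof, the targeted gene, was lower in the knockout at both ages but far from absent. At 8 weeks it stood at -0.70 ± 0.11 (adjusted p = 2.3e-08) in the authors' deposited table, with 14414 normalized counts in the knockout and 23454 in the wild type. At 28 weeks the authors' deposited table gave -1.01 ± 0.16 (adjusted p = 2.5e-06), with 11839 and 23860.3 counts. The knockout mean was thus 61.5% and then 49.6% of the wild-type mean in the authors' deposited table. The deleted part of the gene is not given in the sources used here, so whether the counted reads lie outside it is not known. With age, Apof did not pass the test in wild type (0.18 ± 0.13, adjusted p = 0.581) or knockout (-0.14 ± 0.16, adjusted p = 0.779) in the authors' deposited table. Input reads summed over 3 animals at its deepest site were 36467 in wild type and 21634 in knockout at 8 weeks in the authors' deposited table of sites, and 36192 and 18546 at 28 weeks. Apon, an apolipoprotein gene next to Apof in the GRCm38.p6 annotation, also fell (-0.92 ± 0.25, adjusted p = 0.00939, then -0.78 ± 0.10, adjusted p = 9.3e-11) in the authors' deposited table. It was the one gene called at both ages among 48 tested neighbours within 40 places on either side, of which 2 were called at 8 weeks and 1 at 28 weeks. In the list of Apof locus neighbours fixed beforehand, DESeq2 called 0 of 25 (4 at an unadjusted p under 0.05) at 8 weeks (camera adjusted p = 0.763) and 0 of 24 (3 at an unadjusted p under 0.05) at 28 weeks (camera adjusted p = 0.435).

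The 8-week comparison asked what the knockout changed in the young adult liver. Knockout livers carried more RNA of matrix, cell-cycle and male-biased genes, and less of fatty acid oxidation, female-biased, immediate early and lymphocyte genes. Among 15214 genes tested in the authors' deposited table, 377 were higher and 380 lower in the knockout, of which 238 and 207 differed at least 2-fold. Of 55 genes named by the rule fixed beforehand, 51 passed, and the other 4 had log2 ratios from -1.35 to 0.92 in the authors' deposited table. Y-linked genes were among the largest differences. Ddx3y had 2338 normalized counts in knockout and 0.178 in wild type in the authors' deposited table (adjusted p = 0.0146). Kdm5d had 935 normalized counts in knockout and 0.178 in wild type (adjusted p = 7.8e-04), and Eif2s3y 1392 normalized counts in knockout and 2.96 in wild type (adjusted p = 0.0284), in the authors' deposited table. The 8-week wild-type group thus held almost no Y-linked RNA, which stands beside every 8-week result, every wild-type age result and every difference between the ages below.

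Of 18 male-biased liver genes, 9 rose, 0 fell and 9 did not pass (13 and 0 adjusted over the list alone). The male-biased median was 2.48 (camera adjusted p = 1.3e-15). Cyp4a12a, a fatty acid hydroxylase, had 2489 normalized counts in knockout and 1.92 in wild type (adjusted p = 6.6e-08) in the authors' deposited table. Its near copy Cyp4a12b, with which it can share reads, stood at 7.96 ± 1.60, adjusted p = 8.6e-05 in the authors' deposited table. Of 22 female-biased liver genes, 0 rose, 8 fell and 14 did not pass (0 and 8 adjusted over the list alone). The female-biased median was -1.85 (camera adjusted p = 2.6e-16). Cyp3a41b, a steroid hydroxylase, had 0.189 normalized counts in knockout and 3308 in wild type (adjusted p = 1.9e-28) in the authors' deposited table. Its relatives Cyp3a41a (-5.44 ± 0.30, adjusted p = 1.7e-69) and Cyp3a16 (-3.92 ± 1.01, adjusted p = 0.00471) also fell in the authors' deposited table, and each value is uncertain because such genes share reads. Cyp2u1, a fatty acid hydroxylase (2.26 ± 0.37, adjusted p = 3.7e-07), rose, while Sult3a1, a sulfotransferase (-4.82 ± 1.24, adjusted p = 0.00481), and Ppp1r3g, a glycogen-targeting subunit (-4.06 ± 0.66, adjusted p = 2.0e-07), fell in the authors' deposited table. Akr1c18, a steroid dehydrogenase, had 226 normalized counts in knockout and 0.178 in wild type (adjusted p = 6.9e-04) in the authors' deposited table.

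Lipid genes moved in several directions. Of 27 fatty acid oxidation and PPAR alpha target genes, 0 rose, 11 fell and 16 did not pass (0 and 16 adjusted over the list alone). The fatty acid oxidation median was -0.55 (camera adjusted p = 2.0e-14). Acot1, an acyl-CoA thioesterase (-1.79 ± 0.22, adjusted p = 2.8e-13), and Acaa1b, a peroxisomal thiolase (-1.12 ± 0.20, adjusted p = 4.1e-06), fell in the authors' deposited table. Of 30 lipoprotein transport genes, 2 rose, 3 fell and 25 did not pass (2 and 6 adjusted over the list alone). The lipoprotein median was -0.30 (camera adjusted p = 0.00115). Sort1, a sorting receptor (1.11 ± 0.26, adjusted p = 0.00103), rose, while Lipg, endothelial lipase (-1.53 ± 0.29, adjusted p = 1.9e-05), fell in the authors' deposited table. Of 22 fatty acid and triglyceride synthesis genes, 3 rose, 0 fell and 19 did not pass (4 and 0 adjusted over the list alone). The fatty acid synthesis median was 0.41 (camera adjusted p = 0.0155; adjusted p = 0.0852 at a correlation of 0.05). Acly, which makes acetyl-CoA (1.59 ± 0.41, adjusted p = 0.00516), and Elovl6, an elongase (1.24 ± 0.33, adjusted p = 0.00731), rose in the authors' deposited table. Of 23 cholesterol synthesis genes, DESeq2 called 0, with 4 at an unadjusted p under 0.05. The cholesterol synthesis median was 0.37 (camera adjusted p = 0.0247; adjusted p = 0.111 at a correlation of 0.05). Of 22 lipid droplet and uptake genes, 3 rose, 5 fell and 14 did not pass (3 and 6 adjusted over the list alone). The lipid droplet median was -0.18 (camera adjusted p = 0.123). Lpl, lipoprotein lipase (2.88 ± 0.30, adjusted p = 6.1e-19), rose, while Cd36, a fatty acid transporter (-1.65 ± 0.25, adjusted p = 9.4e-09), fell in the authors' deposited table. Of 19 bile acid genes, 1 rose, 2 fell and 16 did not pass (1 and 2 adjusted over the list alone). The bile acid median was -0.03 (camera adjusted p = 0.661). Slc10a1, the bile acid importer (0.93 ± 0.15, adjusted p = 3.3e-07), rose, while Abcb4, a phospholipid exporter (-0.51 ± 0.11, adjusted p = 5.1e-04), fell in the authors' deposited table.

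Genes of growth and matrix were higher in the 8-week knockout. Of 19 stellate cell, fibroblast and matrix genes, 9 rose, 0 fell and 10 did not pass (13 and 0 adjusted over the list alone). The matrix median was 1.01 (camera adjusted p = 1.4e-13). Col5a1, a fibrillar collagen (1.10 ± 0.16, adjusted p = 1.1e-08), and Col3a1, another (2.21 ± 0.37, adjusted p = 5.2e-07), rose in the authors' deposited table. Of 28 proliferation genes, 10 rose, 0 fell and 18 did not pass (18 and 1 adjusted over the list alone). The proliferation median was 1.80 (camera adjusted p = 1.8e-13). H19, an imprinted RNA of the fetal liver, had 2472 normalized counts in knockout and 22 in wild type (adjusted p = 0.00158) in the authors' deposited table. Ube2c, of mitosis, had 33.6 normalized counts in knockout and 0.177 in wild type (adjusted p = 2.7e-04) in the authors' deposited table. Of 25 m6A writers, erasers and readers, 1 rose, 0 fell and 24 did not pass (1 and 0 adjusted over the list alone). The m6A machinery median was 0.07 (camera adjusted p = 0.0193; adjusted p = 0.105 at a correlation of 0.05; 0.26 by ranks). Igf2bp3, a reader abundant in fetal tissues, rose from 16.7 to 851 normalized counts (5.67 ± 0.35, adjusted p = 4.5e-54) in the authors' deposited table.

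Of 33 xenobiotic metabolism genes, 5 rose, 8 fell and 20 did not pass (5 and 12 adjusted over the list alone). The xenobiotic median was -0.43 (camera adjusted p = 0.00547; adjusted p = 0.0729 at a correlation of 0.05). Cyp2c55, a cytochrome P450 (2.36 ± 0.35, adjusted p = 1.1e-08), rose, while Ugt1a1, which conjugates bilirubin (-1.10 ± 0.12, adjusted p = 4.8e-16), and Nr1i3, a xenobiotic receptor (-1.48 ± 0.25, adjusted p = 9.3e-07), fell in the authors' deposited table. Of 20 immediate early and heat shock genes, 0 rose, 7 fell and 13 did not pass (0 and 9 adjusted over the list alone). The immediate early median was -0.94 (camera adjusted p = 9.6e-09). Dusp1, a stress-induced phosphatase (-2.72 ± 0.49, adjusted p = 7.0e-06), and Zfp36, which destabilises messenger RNAs (-1.41 ± 0.39, adjusted p = 0.00953), fell in the authors' deposited table. Of 19 circadian clock genes, 0 rose, 2 fell and 17 did not pass (0 and 2 adjusted over the list alone). The clock median was -0.59 (camera adjusted p = 0.0143; adjusted p = 0.0729 at a correlation of 0.05). Cry1, a clock repressor (-1.18 ± 0.24, adjusted p = 1.4e-04), and Nfil3, another (-1.13 ± 0.37, adjusted p = 0.043), fell in the authors' deposited table. Of 24 unfolded protein and stress response genes, 2 rose, 0 fell and 22 did not pass (6 and 1 adjusted over the list alone). The unfolded protein median was 0.38 (camera adjusted p = 0.0315; adjusted p = 0.13 at a correlation of 0.05). Asns, asparagine synthetase, had 139 normalized counts in knockout and 7.7 in wild type (adjusted p = 3.0e-04) in the authors' deposited table. Pdia6, a disulfide isomerase (0.72 ± 0.23, adjusted p = 0.0362), rose in the authors' deposited table. Of 16 gluconeogenesis and fasting genes, 1 rose, 0 fell and 15 did not pass (1 and 1 adjusted over the list alone). The gluconeogenesis median was -0.21 (camera adjusted p = 0.12). Pfkfb3, a regulator of glycolysis (1.55 ± 0.47, adjusted p = 0.0287), rose in the authors' deposited table.

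Of 17 lymphocyte and plasma cell markers, 0 rose, 2 fell and 15 did not pass (0 and 3 adjusted over the list alone). The lymphocyte median was -1.11 (camera adjusted p = 5.0e-04). Cd3g, of the T cell receptor (-1.43 ± 0.46, adjusted p = 0.0447), and Cd22, of B cells (-1.22 ± 0.40, adjusted p = 0.048), fell in the authors' deposited table. Of 9 neutrophil and erythroid markers, 2 rose, 0 fell and 7 did not pass (2 and 0 adjusted over the list alone). The erythroid median was 1.32 (camera adjusted p = 2.3e-04). Alas2, an erythroid haem enzyme (2.69 ± 0.36, adjusted p = 4.7e-11), and Hba-a2, a globin (1.45 ± 0.30, adjusted p = 1.2e-04), rose in the authors' deposited table. Of 18 hepatocyte markers, 2 rose, 0 fell and 16 did not pass (4 and 2 adjusted over the list alone). The hepatocyte median was 0.17 (camera adjusted p = 0.86). Alb, albumin (0.62 ± 0.18, adjusted p = 0.0233), and Fgb, a fibrinogen chain (0.71 ± 0.20, adjusted p = 0.0139), rose in the authors' deposited table. Of 22 acute phase genes, 5 rose, 1 fell and 16 did not pass (6 and 2 adjusted over the list alone). The acute phase median was 0.10 (camera adjusted p = 0.366). Fgg, a fibrinogen chain (0.83 ± 0.21, adjusted p = 0.00302), rose, while Orm3, an orosomucoid (-2.06 ± 0.35, adjusted p = 8.4e-07), fell in the authors' deposited table. Of 28 interferon response genes, 3 rose, 0 fell and 25 did not pass (3 and 0 adjusted over the list alone). The interferon median was 0.18 (camera adjusted p = 0.21). Usp18, a protease (0.97 ± 0.27, adjusted p = 0.0122), and Isg15, its ubiquitin-like substrate (0.96 ± 0.29, adjusted p = 0.0234), rose in the authors' deposited table. Of 14 senescence and p53 target genes, 1 rose, 1 fell and 12 did not pass (2 and 1 adjusted over the list alone). The senescence median was 0.01 (camera adjusted p = 0.424). Aen, a nuclease (0.86 ± 0.23, adjusted p = 0.00867), rose, while Trp53inp1, a p53 target (-1.22 ± 0.33, adjusted p = 0.0076), fell in the authors' deposited table. Of 20 Kupffer cell markers, DESeq2 called 0, with 2 at an unadjusted p under 0.05. The Kupffer cell median was -0.20 (camera adjusted p = 0.133). Of 16 sinusoidal endothelial markers, DESeq2 called 0, with 1 at an unadjusted p under 0.05. The endothelial median was 0.02 (camera adjusted p = 0.94). Of 11 cholangiocyte markers, DESeq2 called 0, with 2 at an unadjusted p under 0.05. The cholangiocyte median was 0.19 (camera adjusted p = 0.882). Of 3 adipose, muscle and pancreas markers, DESeq2 called 0, with 0 at an unadjusted p under 0.05. The contaminant median was 1.46 (camera adjusted p = 0.123). Another 9 of these had no adjusted p, all with positive log2 ratios (median 5.24, SE 1.77 to 3.98). In counts simulated at this design, where 99 and 96 of 13979 genes were changed by 1 and 2 log2 units, DESeq2 called 0.501% of the unchanged genes at 8 weeks, which made up 32.7% of its 211 calls. That share depends on how many genes truly change. No correlation between genes could be estimated without values per library, and with a preset of 0.05 in place of 0.01 the camera test passed for 9 lists in place of 15.

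**Figure D1:**
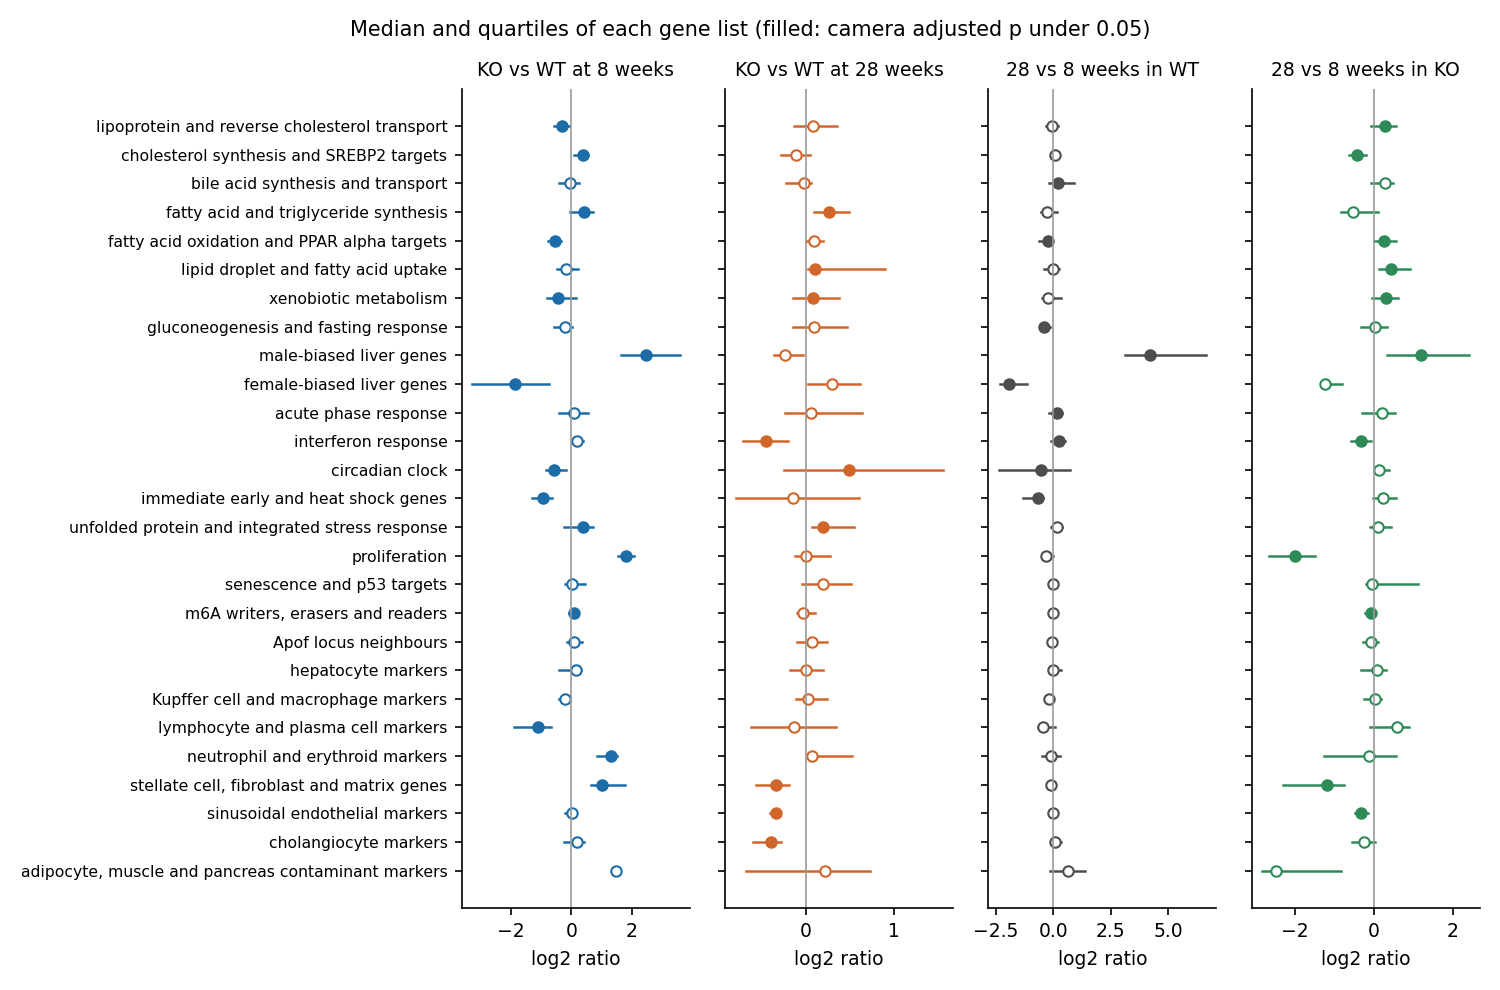
Median log2 ratio (points) and quartiles (lines) of the tested members of 27 gene lists in the 4 RNA comparisons, with a separate log2 axis for each; filled points passed camera at an adjusted p under 0.05. The stellate cell, fibroblast and matrix list had its median at 1.01 in the knockout against wild type at 8 weeks and at -0.34 at 28 weeks.

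The 28-week comparison asked the same question in mature animals, where far fewer genes differed. Endothelial, matrix and interferon genes were lower as lists in the knockout, with few members called. Among 14391 genes tested in the authors' deposited table, 12 were higher and 25 lower, of which 9 and 7 differed at least 2-fold. Of 34 genes named by the rule fixed beforehand, 18 passed, and the other 16 had log2 ratios from -1.20 to 3.17 in the authors' deposited table. Y-linked RNA was spread widely, with Ddx3y at -0.03 ± 2.28, Kdm5d at 0.01 ± 3.22 and Eif2s3y at 0.24 ± 3.30 in the authors' deposited table, while the median SE of all tested genes was 0.254, against 0.263 at 8 weeks. The labels give no sex, and where groups mix sexes, genes that differ by sex have less chance of a call. Noct, a rhythmic phosphatase (3.55 ± 0.85, adjusted p = 0.0178), and Irx1, a transcription factor (1.96 ± 0.33, adjusted p = 1.7e-05), rose in the authors' deposited table. Marchf8, a ubiquitin ligase (1.51 ± 0.38, adjusted p = 0.0383), and Per2, a clock gene (1.44 ± 0.34, adjusted p = 0.0174), rose in the authors' deposited table. Tbc1d16 (1.42 ± 0.32, adjusted p = 0.00772) and Prkcb (1.25 ± 0.23, adjusted p = 1.8e-04) rose in the authors' deposited table. Rsc1a1 (-1.70 ± 0.38, adjusted p = 0.0073) and Pde7b (-1.59 ± 0.41, adjusted p = 0.047) fell in the authors' deposited table. Cdh1, E-cadherin (-1.51 ± 0.34, adjusted p = 0.008), and Csnk1e, a clock kinase (-1.48 ± 0.33, adjusted p = 0.008), fell in the authors' deposited table. Atf7 (-1.33 ± 0.18, adjusted p = 1.6e-09) and Steap3 (-1.04 ± 0.21, adjusted p = 9.1e-04) fell in the authors' deposited table. Of 16 sinusoidal endothelial markers, 0 rose, 2 fell and 14 did not pass (0 and 2 adjusted over the list alone). The endothelial median was -0.34 (camera adjusted p = 9.5e-13). Stab2, a scavenger receptor (-0.67 ± 0.13, adjusted p = 9.1e-04), and Stab1, another (-0.48 ± 0.12, adjusted p = 0.0214), fell in the authors' deposited table. Of 19 stellate cell, fibroblast and matrix genes, 0 rose, 1 fell and 18 did not pass (0 and 4 adjusted over the list alone). The matrix median was -0.34 (camera adjusted p = 3.9e-06). Col4a1, a basement membrane collagen (-0.74 ± 0.17, adjusted p = 0.008), fell in the authors' deposited table. Of 28 interferon response genes, 0 rose, 1 fell and 27 did not pass (0 and 6 adjusted over the list alone). The interferon median was -0.45 (camera adjusted p = 1.9e-10). Rsad2, an antiviral enzyme (-0.99 ± 0.22, adjusted p = 0.00474), fell in the authors' deposited table.

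Of 19 circadian clock genes, 1 rose, 0 fell and 18 did not pass (7 and 3 adjusted over the list alone). The clock median was 0.49 (camera adjusted p = 0.0024; 0.0769 by ranks). Time of harvest is not given and was not tested as a cause, here or with age. Of 30 lipoprotein transport genes, 0 rose, 1 fell and 29 did not pass (0 and 1 adjusted over the list alone). The lipoprotein median was 0.08 (camera adjusted p = 0.679). Apon was the member that fell. Of 10 cholangiocyte markers, DESeq2 called 0, with 0 at an unadjusted p under 0.05. The cholangiocyte median was -0.39 (camera adjusted p = 0.0153; adjusted p = 0.0562 at a correlation of 0.05). Of 21 lipid droplet and uptake genes, DESeq2 called 0, with 3 at an unadjusted p under 0.05. The lipid droplet median was 0.10 (camera adjusted p = 0.00496; adjusted p = 0.0553 at a correlation of 0.05). Of 21 fatty acid and triglyceride synthesis genes, DESeq2 called 0, with 1 at an unadjusted p under 0.05. The fatty acid synthesis median was 0.26 (camera adjusted p = 0.0187; adjusted p = 0.107 at a correlation of 0.05). Of 23 unfolded protein and stress response genes, DESeq2 called 0, with 5 at an unadjusted p under 0.05. The unfolded protein median was 0.19 (camera adjusted p = 0.00874; adjusted p = 0.0699 at a correlation of 0.05). Of 32 xenobiotic metabolism genes, DESeq2 called 0, with 4 at an unadjusted p under 0.05. The xenobiotic median was 0.08 (camera adjusted p = 0.0462; adjusted p = 0.222 at a correlation of 0.05; 0.119 by ranks).

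In the other lists DESeq2 called 0 members and camera did not pass. The members at an unadjusted p under 0.05 were 0 of 27 fatty acid oxidation genes, 0 of 18 male-biased genes, 0 of 3 female-biased genes, 0 of 26 proliferation genes, 1 of 23 cholesterol synthesis genes and 0 of 19 bile acid genes. They were 6 of 21 immediate early genes, 4 of 23 acute phase genes, 2 of 16 gluconeogenesis genes, 1 of 16 senescence genes and 1 of 25 m6A machinery genes. Among markers they were 3 of 18 hepatocyte markers, 0 of 20 Kupffer cell markers, 1 of 15 lymphocyte markers, 0 of 8 neutrophil and erythroid markers and 1 of 3 adipose, muscle and pancreas markers. The other 19 of the 22 female-biased genes had no p at 28 weeks and SE from 1.39 to 3.73, with 13 log2 ratios positive and 6 negative (median 0.61). By the authors' tally, an unadjusted p under 0.05 with more than a 2-fold difference, 215 genes passed in place of 37. With a preset correlation of 0.05 camera passed for 4 lists in place of 9.

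The genotype contrast differed between ages for some genes. The 8-week wild type, with almost no Y-linked RNA, enters each difference, so sex is confounded with it. Of 14278 genes tested at both ages, 225 differed by a Wald test on the difference of the log2 ratios, 112 more positive and 113 more negative at 28 weeks after Benjamini-Hochberg adjustment. The difference, 28 weeks minus 8 weeks, computed from the log2 ratios and SE of the authors' deposited table, was -2.54 ± 0.36, adjusted p = 5.5e-09 for Col4a1, -3.20 ± 0.44, adjusted p = 1.5e-09 for Lpl and -5.32 ± 0.70, adjusted p = 9.6e-11 for Igf2bp3. For Apof, computed likewise from the authors' deposited table, it did not pass (-0.31 ± 0.19, adjusted p = 0.595). Across genes, which are not independent replicates, the log2 ratios of both ages had a Pearson r of -0.056 and a Spearman rho of -0.074. Called at both ages were 7 genes, against 1.80 for independent lists (Fisher's exact test, 2-sided p = 0.00175). Apof, Apon and Csnk1e were lower at both ages, Adprh, Col4a1 and Col4a2 were higher and then lower, and Irx1 was lower and then higher, in the authors' deposited table. Of 26 lists, 12 differed between ages by camera, and 11 with a preset correlation of 0.05. Matrix (camera adjusted p = 1.6e-19) and proliferation genes (7.8e-08) were relatively lower in the knockout at 28 weeks. Fatty acid oxidation (4.2e-09) and lipoprotein genes (3.2e-04) were relatively higher. In the simulated counts the test called 0.363% of unchanged genes, 31.6% of its 158 calls, again above the share of 0.05 that the threshold aims at.

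**Figure D2:**
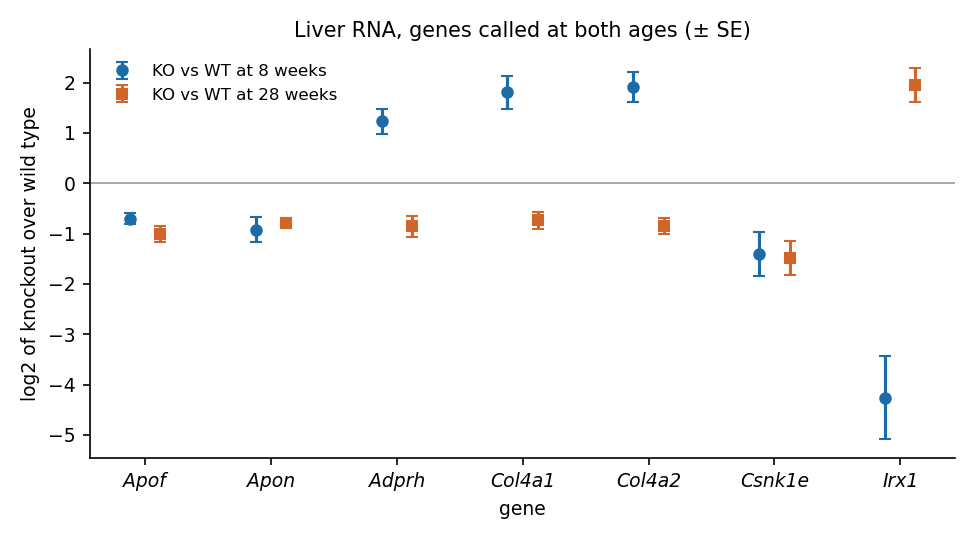
Log2 ratio of knockout over wild type with its SE (bars) from 3 animals per group for the 7 genes called at both ages, at 8 weeks (circles) and 28 weeks (squares). In the authors' deposited table Apof stood at -0.70 and -1.01 and Apon at -0.92 and -0.78, while Irx1 went from -4.26 to 1.96.

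The wild-type age comparison asked how the normal liver changed from 8 to 28 weeks. Male-biased genes rose, and fatty acid oxidation, immediate early, heat shock and clock genes fell as lists. Among 13474 genes tested in the authors' deposited table, 320 rose and 251 fell, of which 168 and 111 did so at least 2-fold. Of 51 genes named by the rule fixed beforehand, 44 passed, and the other 7 had log2 ratios from -3.79 to 0.18 in the authors' deposited table. The 8-week animals are those of the 8-week genotype contrast, so the same chance values enter both. Ddx3y had 2339.6 normalized counts in 28-week and 0.168 in 8-week livers (adjusted p = 0.00153) in the authors' deposited table. Kdm5d had 870.4 normalized counts in 28-week and 0.168 in 8-week livers (adjusted p = 0.0415), and Eif2s3y 1273 normalized counts in 28-week and 2.79 in 8-week (adjusted p = 0.0304), in the authors' deposited table. Of 18 male-biased liver genes, 16 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone). The male-biased median was 4.19 (camera adjusted p = 2.9e-30). Cyp4a12a had 8366 normalized counts in 28-week and 1.81 in 8-week livers (adjusted p = 5.1e-06), and Cyp4a12b 2871 normalized counts in 28-week and 2.7 in 8-week (adjusted p = 9.7e-05), in the authors' deposited table. Hsd3b5, a steroid reductase (6.89 ± 1.3, adjusted p = 3.0e-05), and Mup7, a urinary protein (7.67 ± 1.5, adjusted p = 6.5e-05), rose in the authors' deposited table. Serpina1e, a protease inhibitor of a family that, like Mup, shares reads (2.0 ± 0.35, adjusted p = 3.7e-06), rose in the authors' deposited table. Of 17 female-biased liver genes with a p, DESeq2 called 0, with 4 at an unadjusted p under 0.05. The female-biased median was -1.93 (camera adjusted p = 0.0129; adjusted p = 0.0877 at a correlation of 0.05). Capn8, a calpain, had 239.9 normalized counts in 28-week and 0.168 in 8-week livers (adjusted p = 4.8e-04) in the authors' deposited table. Rad51b, of DNA repair (-4.38 ± 1.41, adjusted p = 0.0466), and Usp2, a rhythmic protease (-4.07 ± 0.87, adjusted p = 3.4e-04), fell in the authors' deposited table. Ciart, a clock repressor (-3.41 ± 1.09, adjusted p = 0.0441), and Tcf24, a transcription factor (-3.07 ± 0.69, adjusted p = 8.3e-04), fell in the authors' deposited table. Cyp4a14, a fatty acid hydroxylase (-2.89 ± 0.92, adjusted p = 0.042), and Noct (-2.88 ± 0.93, adjusted p = 0.049) fell in the authors' deposited table.

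Of 20 immediate early and heat shock genes, 0 rose, 6 fell and 14 did not pass (0 and 7 adjusted over the list alone). The immediate early median was -0.65 (camera adjusted p = 7.2e-12). Hspa8, a chaperone (-1.27 ± 0.12, adjusted p = 3.5e-23), and Dnajb1, its partner (-1.07 ± 0.15, adjusted p = 3.2e-10), fell in the authors' deposited table. Of 19 circadian clock genes, 2 rose, 7 fell and 10 did not pass (4 and 10 adjusted over the list alone). The clock median was -0.51 (camera adjusted p = 0.004). Clock, a core activator (1.35 ± 0.27, adjusted p = 1.1e-04), rose, while Dbp, a clock output factor (-2.25 ± 0.43, adjusted p = 3.2e-05), fell in the authors' deposited table. Of 27 fatty acid oxidation and PPAR alpha target genes, 0 rose, 3 fell and 24 did not pass (0 and 6 adjusted over the list alone). The fatty acid oxidation median was -0.23 (camera adjusted p = 6.5e-06). Acot1 (-1.14 ± 0.28, adjusted p = 0.00277) and Acadl, a dehydrogenase (-0.55 ± 0.12, adjusted p = 3.9e-04), fell in the authors' deposited table. Of 16 gluconeogenesis and fasting genes, 0 rose, 1 fell and 15 did not pass (0 and 1 adjusted over the list alone). The gluconeogenesis median was -0.41 (camera adjusted p = 0.0195; adjusted p = 0.0877 at a correlation of 0.05). Tat, tyrosine aminotransferase (-1.0 ± 0.29, adjusted p = 0.0233), fell in the authors' deposited table. Of 19 bile acid genes, 5 rose, 1 fell and 13 did not pass (7 and 3 adjusted over the list alone). The bile acid median was 0.23 (camera adjusted p = 0.0264; adjusted p = 0.12 at a correlation of 0.05; 0.203 by ranks). Acox2, which shortens the side chain (0.93 ± 0.16, adjusted p = 5.3e-06), rose, while Cyp7a1, the rate-limiting enzyme (-1.92 ± 0.35, adjusted p = 1.7e-05), fell in the authors' deposited table. Of 22 acute phase genes, 5 rose, 0 fell and 17 did not pass (6 and 2 adjusted over the list alone). The acute phase median was 0.15 (camera adjusted p = 0.0363; adjusted p = 0.159 at a correlation of 0.05; 0.158 by ranks). Fgg (0.66 ± 0.16, adjusted p = 0.00302) and Fgb (0.53 ± 0.13, adjusted p = 0.00431) rose in the authors' deposited table. Of 28 interferon response genes, 5 rose, 0 fell and 23 did not pass (5 and 0 adjusted over the list alone). The interferon median was 0.25 (camera adjusted p = 0.0105; adjusted p = 0.0877 at a correlation of 0.05). Rsad2 (1.31 ± 0.30, adjusted p = 0.00105) and Oasl1, an antiviral effector (1.10 ± 0.25, adjusted p = 8.9e-04), rose in the authors' deposited table.

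Of 30 lipoprotein transport genes, 2 rose, 4 fell and 24 did not pass (4 and 6 adjusted over the list alone). The lipoprotein median was -0.05 (camera adjusted p = 0.334). Apon (0.57 ± 0.11, adjusted p = 5.8e-05) rose, while Lipg (-2.10 ± 0.34, adjusted p = 4.1e-07) fell in the authors' deposited table. Of 23 cholesterol synthesis genes, 1 rose, 2 fell and 20 did not pass (2 and 2 adjusted over the list alone). The cholesterol synthesis median was 0.07 (camera adjusted p = 0.294). Dhcr7, a late enzyme (0.60 ± 0.13, adjusted p = 5.0e-04), rose in the authors' deposited table. Of 20 fatty acid and triglyceride synthesis genes, 0 rose, 1 fell and 19 did not pass (1 and 4 adjusted over the list alone). The fatty acid synthesis median was -0.29 (camera adjusted p = 0.106). Fads2, a desaturase (-0.89 ± 0.26, adjusted p = 0.023), fell in the authors' deposited table. Of 21 lipid droplet and uptake genes, 1 rose, 1 fell and 19 did not pass (1 and 4 adjusted over the list alone). The lipid droplet median was 0.00 (camera adjusted p = 0.516). Fitm1, of droplet formation (2.55 ± 0.66, adjusted p = 0.00584), rose, while Mgll, a lipase (-0.71 ± 0.20, adjusted p = 0.017), fell in the authors' deposited table. Of 33 xenobiotic metabolism genes, 1 rose, 7 fell and 25 did not pass (5 and 8 adjusted over the list alone). The xenobiotic median was -0.23 (camera adjusted p = 0.0933). Por, the cytochrome P450 reductase (-1.68 ± 0.34, adjusted p = 1.2e-04), and Cyp2c37 (-1.40 ± 0.20, adjusted p = 8.3e-09) fell in the authors' deposited table. Of 22 unfolded protein and stress response genes, 2 rose, 1 fell and 19 did not pass (4 and 1 adjusted over the list alone). The unfolded protein median was 0.16 (camera adjusted p = 0.179). Pdia4, a disulfide isomerase (0.60 ± 0.16, adjusted p = 0.00581), and Trib3, a pseudokinase (1.23 ± 0.35, adjusted p = 0.0149), rose in the authors' deposited table. Of 24 Apof locus neighbours, 0 rose, 3 fell and 21 did not pass (0 and 3 adjusted over the list alone). The Apof locus median was -0.06 (camera adjusted p = 0.101). Hsd17b6, a steroid dehydrogenase (-0.80 ± 0.17, adjusted p = 3.5e-04), and Rdh9, a retinol dehydrogenase (-0.85 ± 0.19, adjusted p = 5.1e-04), fell in the authors' deposited table.

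Of 18 hepatocyte markers, 3 rose, 1 fell and 14 did not pass (4 and 1 adjusted over the list alone). The hepatocyte median was 0.01 (camera adjusted p = 0.185). Serpina1c, of a family that shares reads (0.60 ± 0.11, adjusted p = 7.7e-06), rose in the authors' deposited table. Of 6 neutrophil and erythroid markers, 1 rose, 0 fell and 5 did not pass (1 and 0 adjusted over the list alone). The erythroid median was -0.09 (camera adjusted p = 0.726). Alas2 (3.01 ± 0.97, adjusted p = 0.0453) rose in the authors' deposited table. Of 11 cholangiocyte markers, 1 rose, 0 fell and 10 did not pass (1 and 0 adjusted over the list alone). The cholangiocyte median was 0.10 (camera adjusted p = 0.294). Sox9, a duct transcription factor (1.38 ± 0.28, adjusted p = 1.2e-04), rose in the authors' deposited table. DESeq2 called 0 members of 8 other lists, and camera did not pass for them or, for adipose, muscle and pancreas markers, was not run. At an unadjusted p under 0.05 were 2 of 22 proliferation, 1 of 13 senescence, 1 of 25 m6A machinery and 1 of 18 matrix genes. So were 2 of 19 Kupffer cell, 1 of 14 lymphocyte, 0 of 16 endothelial and 1 of 2 adipose, muscle and pancreas markers. With a preset correlation of 0.05 camera passed for 4 lists in place of 9.

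The knockout age comparison covered the same interval. Matrix, cell-cycle and endothelial genes fell as lists. Among 14798 genes tested in the authors' deposited table, 301 rose and 364 fell, of which 157 and 280 did so at least 2-fold. Of 53 genes named by the rule fixed beforehand, 43 passed, and the other 10 had log2 ratios from -1.58 to 1.48 in the authors' deposited table. Its groups are those of the 8-week and 28-week genotype contrasts. Of 19 stellate cell, fibroblast and matrix genes, 0 rose, 11 fell and 8 did not pass (0 and 12 adjusted over the list alone). The matrix median was -1.18 (camera adjusted p = 2.5e-42). Col1a2 (-2.66 ± 0.22, adjusted p = 1.3e-30) and Col1a1 (-2.69 ± 0.24, adjusted p = 1.1e-25) fell in the authors' deposited table. Col4a1 (-2.08 ± 0.20, adjusted p = 2.6e-21) and Fbn1, a microfibril gene (-2.34 ± 0.23, adjusted p = 3.8e-21), fell in the authors' deposited table. Of 28 proliferation genes, 0 rose, 10 fell and 18 did not pass (0 and 18 adjusted over the list alone). The proliferation median was -2.0 (camera adjusted p = 1.3e-14). H19 had 7.18 normalized counts in 28-week and 2357 in 8-week livers (adjusted p = 4.2e-04) in the authors' deposited table. Mcm6, of DNA replication (-2.74 ± 0.49, adjusted p = 5.0e-06), fell in the authors' deposited table. Of 25 m6A writers, erasers and readers, 0 rose, 1 fell and 24 did not pass (0 and 1 adjusted over the list alone). The m6A machinery median was -0.08 (camera adjusted p = 0.025; adjusted p = 0.145 at a correlation of 0.05; 0.194 by ranks). Igf2bp3 fell from 812 to 24.4 normalized counts (-5.06 ± 0.36, adjusted p = 1.5e-40) in the authors' deposited table. Of 16 sinusoidal endothelial markers, 0 rose, 4 fell and 12 did not pass (0 and 4 adjusted over the list alone). The endothelial median was -0.31 (camera adjusted p = 5.0e-04). Stab2 (-0.79 ± 0.16, adjusted p = 1.8e-04) and Cdh5, an endothelial cadherin (-0.66 ± 0.17, adjusted p = 0.00563), fell in the authors' deposited table.

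Of 30 lipoprotein transport genes, 5 rose, 0 fell and 25 did not pass (8 and 1 adjusted over the list alone). The lipoprotein median was 0.29 (camera adjusted p = 0.00203; adjusted p = 0.0573 at a correlation of 0.05). Apoe, which directs remnant clearance (1.14 ± 0.31, adjusted p = 0.0107), and Apoc3, which slows it (0.86 ± 0.21, adjusted p = 0.00319), rose in the authors' deposited table. Of 27 fatty acid oxidation and PPAR alpha target genes, 2 rose, 0 fell and 25 did not pass (6 and 0 adjusted over the list alone). The fatty acid oxidation median was 0.27 (camera adjusted p = 0.00301; adjusted p = 0.0573 at a correlation of 0.05). Cpt2, of the carnitine shuttle (0.70 ± 0.19, adjusted p = 0.0122), and Acadm, a dehydrogenase (0.53 ± 0.16, adjusted p = 0.0323), rose in the authors' deposited table. Of 21 lipid droplet and uptake genes, 4 rose, 2 fell and 15 did not pass (6 and 2 adjusted over the list alone). The lipid droplet median was 0.44 (camera adjusted p = 0.025; adjusted p = 0.144 at a correlation of 0.05). Mfsd2a, a lysophospholipid transporter (2.25 ± 0.45, adjusted p = 9.0e-05), rose, while Lpl (-2.81 ± 0.22, adjusted p = 3.0e-32) fell in the authors' deposited table. Of 23 cholesterol synthesis genes, DESeq2 called 0, with 2 at an unadjusted p under 0.05. The cholesterol synthesis median was -0.43 (camera adjusted p = 0.025; adjusted p = 0.144 at a correlation of 0.05). Of 22 fatty acid and triglyceride synthesis genes, 2 rose, 3 fell and 17 did not pass (2 and 5 adjusted over the list alone). The fatty acid synthesis median was -0.52 (camera adjusted p = 0.0619). Acaca, acetyl-CoA carboxylase (-1.18 ± 0.27, adjusted p = 0.00127), and Elovl6 (-1.35 ± 0.33, adjusted p = 0.00308) fell in the authors' deposited table. Of 19 bile acid genes, 1 rose, 2 fell and 16 did not pass (1 and 2 adjusted over the list alone). The bile acid median was 0.30 (camera adjusted p = 0.128). Cyp7b1, of the alternative pathway (3.66 ± 1.08, adjusted p = 0.0218), rose, while Cyp7a1 (-1.32 ± 0.39, adjusted p = 0.0224) fell in the authors' deposited table.

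Of 18 male-biased liver genes, 3 rose, 0 fell and 15 did not pass (3 and 0 adjusted over the list alone). The male-biased median was 1.19 (camera adjusted p = 0.00901; adjusted p = 0.0629 at a correlation of 0.05). Mup15 (4.85 ± 1.18, adjusted p = 0.00279), Mup1 (4.72 ± 1.34, adjusted p = 0.0157) and Mup12 (4.52 ± 1.28, adjusted p = 0.0149) rose in the authors' deposited table. Mup genes share reads, so each value is uncertain. Of 5 female-biased liver genes with a p, DESeq2 called 0, with 1 at an unadjusted p under 0.05. The female-biased median was -1.23 (camera adjusted p = 0.166). The other 17 of the 22 female-biased genes had no p with age and SE from 1.15 to 3.91, with 12 log2 ratios positive and 5 negative (median 1.53). Of those, Cyp3a41a stood at 6.08 ± 1.98 in the authors' deposited table. Tmem28, a membrane protein, had 213 normalized counts in 28-week and 0.18 in 8-week livers (adjusted p = 8.6e-10) in the authors' deposited table. Akap2, a kinase anchor, had 0.186 normalized counts in 28-week and 325 in 8-week (adjusted p = 6.2e-15), and Akr1c18 0.186 normalized counts in 28-week and 215 in 8-week (adjusted p = 9.4e-04), in the authors' deposited table. Irx1 (6.01 ± 0.61, adjusted p = 4.1e-20) rose, while Tcf24 (-4.89 ± 1.43, adjusted p = 0.0204) and Wdr89 (-3.83 ± 0.62, adjusted p = 1.6e-07) fell in the authors' deposited table. Of 32 xenobiotic metabolism genes, 0 rose, 1 fell and 31 did not pass (4 and 2 adjusted over the list alone). The xenobiotic median was 0.32 (camera adjusted p = 0.025; adjusted p = 0.153 at a correlation of 0.05). Gstm3, a glutathione transferase (-1.46 ± 0.44, adjusted p = 0.0239), fell in the authors' deposited table. Of 28 interferon response genes, 0 rose, 1 fell and 27 did not pass (0 and 1 adjusted over the list alone). The interferon median was -0.32 (camera adjusted p = 0.025; adjusted p = 0.145 at a correlation of 0.05). Usp18 (-1.46 ± 0.34, adjusted p = 0.00118) fell in the authors' deposited table. Of 16 gluconeogenesis and fasting genes, 0 rose, 1 fell and 15 did not pass (0 and 1 adjusted over the list alone). The gluconeogenesis median was 0.04 (camera adjusted p = 0.813). Igfbp1, which binds growth factors (-2.33 ± 0.44, adjusted p = 2.1e-05), fell in the authors' deposited table.

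Of 22 acute phase genes, 2 rose, 1 fell and 19 did not pass (3 and 2 adjusted over the list alone). The acute phase median was 0.22 (camera adjusted p = 0.777). Steap4, a metalloreductase (0.55 ± 0.14, adjusted p = 0.00642), rose, while Apcs, serum amyloid P (-1.38 ± 0.34, adjusted p = 0.00287), fell in the authors' deposited table. Of 19 circadian clock genes, 2 rose, 0 fell and 17 did not pass (2 and 0 adjusted over the list alone). The clock median was 0.14 (camera adjusted p = 0.0867). Nfil3 (1.14 ± 0.35, adjusted p = 0.0274) and Bhlhe41, a clock repressor (1.79 ± 0.54, adjusted p = 0.0256), rose in the authors' deposited table. Of 16 senescence and p53 target genes, 1 rose, 0 fell and 15 did not pass (1 and 0 adjusted over the list alone). The senescence median was -0.05 (camera adjusted p = 0.557). Trp53inp1 (1.05 ± 0.29, adjusted p = 0.0122) rose in the authors' deposited table. Of 18 hepatocyte markers, 2 rose, 2 fell and 14 did not pass (2 and 2 adjusted over the list alone). The hepatocyte median was 0.07 (camera adjusted p = 0.932). Apoa2 (0.50 ± 0.14, adjusted p = 0.0122) rose, while Ahsg, fetuin A (-1.29 ± 0.25, adjusted p = 6.3e-05), fell in the authors' deposited table. Of 15 lymphocyte and plasma cell markers, 1 rose, 1 fell and 13 did not pass (1 and 1 adjusted over the list alone). The lymphocyte median was 0.58 (camera adjusted p = 0.325). Jchain, of secreted antibodies (3.49 ± 0.98, adjusted p = 0.0146), rose, while Gzma, a granzyme (-4.43 ± 1.35, adjusted p = 0.0294), fell in the authors' deposited table. Of 11 neutrophil and erythroid markers, 0 rose, 1 fell and 10 did not pass (0 and 3 adjusted over the list alone). The erythroid median was -0.12 (camera adjusted p = 0.214). Hba-a2 (-1.16 ± 0.32, adjusted p = 0.0106) fell in the authors' deposited table. Of 10 cholangiocyte markers, 1 rose, 0 fell and 9 did not pass (1 and 0 adjusted over the list alone). The cholangiocyte median was -0.24 (camera adjusted p = 0.777). Tspan8 had 26.1 normalized counts in 28-week and 0.179 in 8-week livers (adjusted p = 2.8e-04) in the authors' deposited table. DESeq2 called 0 members of 5 other lists, for which camera did not pass. At an unadjusted p under 0.05 were 2 of 22 immediate early genes, 5 of 24 unfolded protein genes, 6 of 25 Apof locus neighbours, 1 of 20 Kupffer cell markers and 1 of 3 adipose, muscle and pancreas markers. Another 9 of that last list had no adjusted p, all negative (median -4.91, SE 1.72 to 3.98). With a preset correlation of 0.05 camera passed for 3 lists in place of 11.

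The m6A tables asked which methylated sites differed, as IP over input. Each lists sites by gene symbol, without positions, with reads summed over the 3 animals of a group. Their p-values matched the counting error of these sums at 100% of sites within 0.001, so a call compares pooled reads and carries no spread between animals. At 8 weeks sites of lipid enzymes and apolipoproteins were called in both directions. Among 52025 sites in the authors' deposited table, 1420 were called higher and 1396 lower in the knockout, in 2181 genes, with 11 and 149 at least 2-fold. Median IP over input was 0.969 in wild type and 1.10 in knockout, and 1.26% and 2.73% of sites with at least 50 reads reached 2-fold enrichment. Unequal pull-down between the groups is therefore not excluded. Among sites with at least 5000 reads in every sum 51.6% were called, against 1.46% of those with 50 to 200. With the statistic scaled to its own spread at each depth, 397 sites were called in place of 2816, 62 higher and 335 lower.

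Highest at 8 weeks in the authors' deposited table were sites in Ddx3y (2.64, adjusted p = 2.5e-14), Nsmce4a (2.08, adjusted p = 0.00304), Fga (1.99, adjusted p = 7.9e-19) and Loxl1 (1.63, adjusted p = 0.0247). Lowest in the authors' deposited table were sites in Otulinl (-2.61, adjusted p = 0.0191), Epop (-2.41, adjusted p = 0.0318), Plekha3 (-2.39, adjusted p = 1.7e-07) and Cyp3a41a (-2.35, adjusted p = 3.6e-40). Called sites in the authors' deposited table were 13 higher and 9 lower of 137 in lipoprotein genes, 9 higher and 9 lower of 96 in cholesterol synthesis genes and 16 higher and 7 lower of 107 in bile acid genes. They were 15 higher and 12 lower of 132 in fatty acid synthesis genes, 15 higher and 10 lower of 101 in fatty acid oxidation genes, 4 higher and 2 lower of 68 in lipid droplet genes and 4 higher and 4 lower of 122 in m6A machinery genes. Of all sites 5.41% were called, against 8.82 to 24.8% in the lipid lists, whose sites were deeper (median smallest sum 180 to 1292 reads, against 130). Among them in the authors' deposited table were Apoa1 (-0.17, adjusted p = 0), Scd1 (-0.22, adjusted p = 0), Slco1b2 (0.17, adjusted p = 3.6e-30) and Fabp1 (-0.13, adjusted p = 2.0e-197). With one offset for all sites, 18 of 22 called sites the rule named stayed called, Otulinl, Epop and Plekha3 not among them. With the scaled statistic 14 did. The Apof site was not called (0.02, adjusted p = 0.45) in the authors' deposited table.

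At 28 weeks most called sites were lower in the knockout. Among 52315 sites in the authors' deposited table, 481 were called higher and 1241 lower, in 1384 genes, with 4 and 35 at least 2-fold. Highest at 28 weeks in the authors' deposited table were sites in Mup21 (2.20, adjusted p = 1.3e-100), Fga (1.98, adjusted p = 4.8e-24), Zbtb37 (1.49, adjusted p = 0.007) and Mup8 (1.38, adjusted p = 0), the Mup genes sharing reads. Lowest at 28 weeks in the authors' deposited table were sites in Zfp281 (-1.94, adjusted p = 0.00603), Keap1 (-1.66, adjusted p = 0.0418), Tfeb (-1.61, adjusted p = 0.0374) and Ptp4a2 (-1.57, adjusted p = 0.00171). Called 28-week sites in the authors' deposited table were 8 higher and 15 lower of 142 in lipoprotein genes, 2 higher and 8 lower of 94 in cholesterol synthesis genes and 7 higher and 13 lower of 103 in bile acid genes. They were 1 higher and 14 lower of 136 in fatty acid synthesis genes, 10 higher and 11 lower of 108 in fatty acid oxidation genes, 0 higher and 5 lower of 68 in lipid droplet genes and 0 higher and 3 lower of 132 in m6A machinery genes. Of all sites, again less deep, 3.29% were called. Among them in the authors' deposited table were Scd1 (-0.27, adjusted p = 0) and Cyp4a10 (-1.01, adjusted p = 7.4e-22). Sites in Apof stood at 0.16, adjusted p = 0.547 and -0.05, adjusted p = 0.0443 in the authors' deposited table. Median IP over input was 1.16 in wild type and 1.11 in knockout. Of sites with at least 50 reads 6.31% and 2.65% were at least 2-fold enriched, so unequal pull-down is not excluded. The scaled statistic called 246 sites in place of 1722, 82 higher and 164 lower. Of 22 called sites the rule named, 17 stayed called with one offset, without Zfp281, Keap1, Tfeb, Ptp4a2 and Apof, and 9 with the scaled statistic.

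In wild-type livers most sites called between ages were higher at 28 weeks. Among 51883 sites in the authors' deposited table, 1868 were called higher and 454 lower, in 1785 genes, with 14 and 21 at least 2-fold. Highest with age in the authors' deposited table were sites in Lmbrd1 (2.39, adjusted p = 0), E2f6 (1.63, adjusted p = 0.00793), Zfp62 (1.56, adjusted p = 0.032) and Hmgb3 (1.5, adjusted p = 0.00324). Lowest with age in the authors' deposited table were sites in Smyd1 (-8.09, adjusted p = 2.9e-133), Cyp2d11 (-3.71, adjusted p = 6.2e-145), Arid1a (-2.67, adjusted p = 0.0192) and Dvl3 (-2.63, adjusted p = 8.4e-05). Smyd1 had 17254 IP and 39 input reads at 8 weeks, and 116 and 60 at 28 weeks. The cause of this was not tested. Called age-related sites in the authors' deposited table were 12 higher and 7 lower of 140 in lipoprotein genes, 9 higher and 2 lower of 89 in cholesterol synthesis genes and 16 higher and 5 lower of 109 in bile acid genes. They were 28 higher and 3 lower of 133 in fatty acid synthesis genes, 17 higher and 4 lower of 108 in fatty acid oxidation genes, 5 higher and 1 lower of 66 in lipid droplet genes and 6 higher and 1 lower of 122 in m6A machinery genes. Of all sites, again less deep, 4.48% were called. Among them in the authors' deposited table were Thrsp (0.32, adjusted p = 7.6e-69) and Alkbh5, an m6A eraser (-0.85, adjusted p = 9.0e-06). Sites in Apof stood at -0.22, adjusted p = 0.23, -0.22, adjusted p = 0.265 and 0.04, adjusted p = 0.0657 in the authors' deposited table. Median IP over input was 0.966 at 8 and 1.17 at 28 weeks, and the scaled statistic called 223 sites in place of 2322, 136 higher and 87 lower. Of 22 called sites the rule named, 17 stayed called with one offset, without E2f6, Zfp62, Fabp1, Cd36 and Hnrnpa2b1, and 12 with the scaled statistic.

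**Figure D3:**
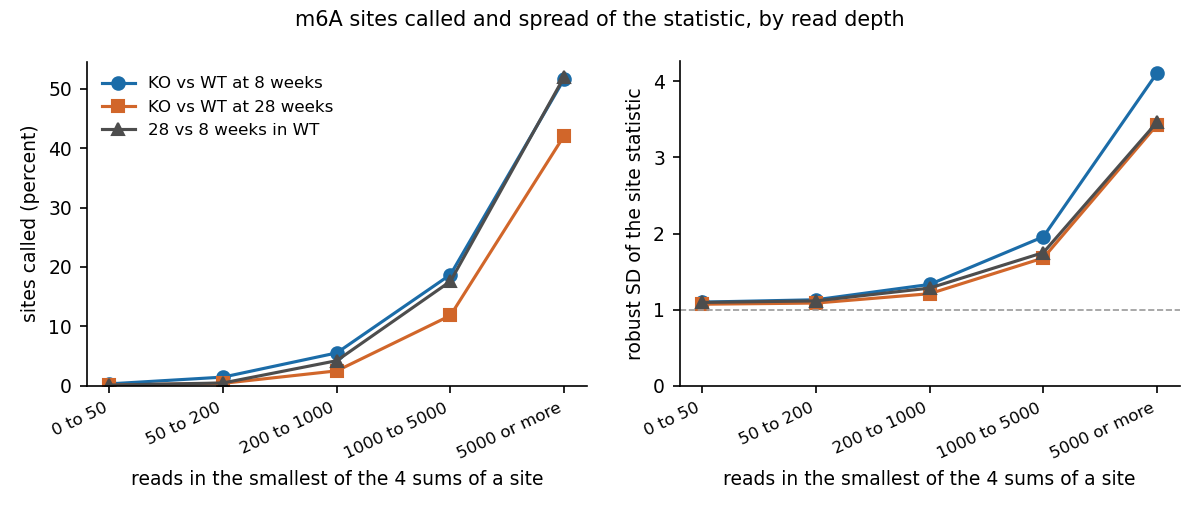
Percent of m6A sites called in the authors' deposited table (left) and robust SD of the site statistic (right) by the reads in the smallest of a site's 4 sums, for 3 comparisons; the dashed line marks an SD of 1, the value for counting error alone. At 8 weeks 51.6% of sites with at least 5000 reads were called and the SD was 4.11.

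The site table of the knockout age comparison carries human-style symbols and is not used here. Its contrast was computed instead at 13823 sites, in 8108 genes, with the same symbol and wild-type read sums in the other 3 tables. The pooled counting test called 315 of them higher and 114 lower at 28 weeks in the knockout, and the genotype difference changed with age at 620. Of these sites 1021 were called at 8 weeks, 593 at 28 weeks and 267 at both, against 43.8 for independent lists, and 188 of the 267 had the same direction. Deep sites are called more often at either age, so this overlap reflects depth as well. The genotype differences at both ages had a Pearson r of 0.0125 and a Spearman rho of 0.0096 across these sites, and a rho of 0.17 over the 2200 with at least 1000 reads in every sum.

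Last, m6A and RNA differences were compared across genes, which are not independent replicates. With the site of smallest p per gene the Spearman rho was -0.11 over 12532 genes at 8 weeks, -0.080 over 12302 at 28 weeks and -0.16 over 12130 with age in wild type. The input libraries enter both measures, as the divisor of the m6A ratio. Genes called for RNA carried a called site more often at 8 weeks (158 genes, 119 expected, odds ratio 1.5, Fisher's exact test, 2-sided p = 5.7e-05). They did so with age in wild type (129 genes, 87.7 expected, odds ratio 1.73, Fisher's exact p = 1.4e-06). At 28 weeks 3 genes were called for both, against 4.14 expected (odds ratio 0.687, Fisher's exact p = 0.787). Within 10 bins of expression level the odds ratios were 1.24, 0.814 and 1.36 for 8 weeks, 28 weeks and wild-type age.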

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

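Among the tests below, those of sex, of exchanged libraries, of hepatocyte share, of random gene sets and of spread between animals were chosen only after the results were seen. The results next stand out because the genotype difference itself differed between ages by a Wald test or by camera, given as 28 weeks minus 8 weeks on the log2 scale. The differences and their adjusted p were computed here from the log2 ratios and SE of each age in the authors' deposited table. The 8-week wild type, with almost no Y-linked RNA, enters each, so sex is confounded with age in all.

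Matrix and growth genes were relatively lower in the knockout at 28 weeks: Col4a1 (-2.54, adjusted p = 5.5e-09), Col1a2 (-2.49, adjusted p = 7.9e-06), Col1a1 (-2.85, adjusted p = 2.0e-04) and Col3a1 (-2.61, adjusted p = 2.9e-06). So were Col5a1 (-1.74, adjusted p = 5.4e-06), Fbn1 (-2.21, adjusted p = 5.4e-06), Igf2bp3 (-5.32, adjusted p = 9.6e-11) and Cdh1 (-2.28, adjusted p = 2.0e-04). As lists, the median of the difference was lower for matrix genes (-1.20, adjusted p = 1.6e-19), proliferation genes (-1.84, adjusted p = 7.8e-08) and endothelial markers (-0.37, adjusted p = 0.00691). Interferon genes were lower as well, with Usp18 (-2.11, adjusted p = 3.5e-04), Isg15 (-1.72, adjusted p = 0.00551) and Rsad2 (-1.88, adjusted p = 0.0241), and their list (-0.65, adjusted p = 4.2e-06). Lipid genes went both ways, with Lpl (-3.20, adjusted p = 1.5e-09) and Slc10a1 (-1.22, adjusted p = 8.7e-04) lower. Higher were Lipg (2.06, adjusted p = 0.00375), Acaa1b (1.43, adjusted p = 0.0127), Mgll (1.15, adjusted p = 0.00715), Acadm (0.75, adjusted p = 0.0198) and Mfsd2a (4.80, adjusted p = 0.0422). The lists were higher for lipoprotein (0.49, adjusted p = 3.2e-04), fatty acid oxidation (0.67, adjusted p = 4.2e-09) and lipid droplet genes (0.44, adjusted p = 0.0127; 0.071 at a preset correlation of 0.05), and lower for cholesterol synthesis (-0.36, adjusted p = 0.00259). Of clock and rhythmic genes Noct (4.42, adjusted p = 0.0278), Per2 (2.10, adjusted p = 0.0294) and Usp2 (4.14, adjusted p = 0.0155) were higher, as was the clock list (0.83, adjusted p = 3.3e-05). The heat shock gene Hspa8 (1.33, adjusted p = 0.00302) was higher, as was the immediate early list (0.80, adjusted p = 5.4e-05). Of xenobiotic genes Ugt1a1 (1.14, adjusted p = 0.0371), Nr1i3 (1.72, adjusted p = 0.00944) and Cyp2c37 (1.84, adjusted p = 2.2e-04) were higher and Cyp2c55 (-2.65, adjusted p = 0.00825) and Gstm3 (-2.04, adjusted p = 0.00599) lower, with the list (0.36, adjusted p = 9.1e-04) higher. Of sex-related genes Cyp4a12a (-11.13, adjusted p = 0.00955) and the male-biased list (-2.84, adjusted p = 4.3e-07) were lower. The 8-week level of Cyp4a12a in wild type was near 0, so its value is no measure of size. Of other genes Irx1 (6.21, adjusted p = 7.6e-09), Tbc1d16 (1.68, adjusted p = 0.00157) and Trp53inp1 (1.27, adjusted p = 0.0421) were higher. Lower were Fgg (-1.05, adjusted p = 0.00302), Fgb (-0.97, adjusted p = 0.0043) and Ahsg (-1.28, adjusted p = 0.0457). So were Wdr89 (-4.18, adjusted p = 1.2e-06), Atf7 (-1.59, adjusted p = 0.00139) and Steap3 (-1.07, adjusted p = 0.0323).

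One table stood outside the comparisons. In the site table of the knockout age comparison 98.9% of 15604 symbols were in capitals only and 995 were human-style antisense or LINC names, against 0 in each of the other 3 tables. No biological explanation was tested for it.

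The first pattern weighed was that male-biased liver genes were higher and female-biased genes lower in the 8-week knockout than in wild type. An exchange of all libraries between the groups is argued against by Apof, which stood at -0.70 ± 0.11 in the authors' deposited table. A difference in the sex of the animals may account for the pattern, since 4 of 4 Y-linked genes in 8-week wild type were under 1% of their level in 8-week knockout. The labels give no sex, so neither a planned nor an unplanned difference in sex can be excluded, and genotype and sex are confounded in this contrast. An effect of the knockout on these genes stays open and untested.

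The second pattern was that growth, matrix and early-life genes were higher in the 8-week knockout. Sex alone would raise them in the wild-type age contrast too, where Y-linked RNA differed as much. There the median of 20 genes of the pattern was -0.085 (95% bootstrap interval over genes -0.16 to 0.22), against 1.81 at 8 weeks. A fall with age could hide a rise by sex, so sex stays open. A lower share of hepatocytes, with all other cell types raised alike, is argued against by the Kupffer cell and endothelial medians, -0.20 and 0.017. Less mature livers in that group may account for it, since over 17 genes that decline after birth, listed after the pattern was seen, the median was 1.15 at 8 weeks, against -0.24 to 0.33 in 95% of 10000 random sets of genes of like level, which share no regulation. The median of -1.17 over 16 of the list with age in the knockout shares the 8-week knockout animals, so it is no independent test. Whether this would reflect genotype, animals younger than labelled or litter stays open and untested, as do non-liver tissue and more matrix cells alone.

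The third pattern was the 2816 m6A sites called at 8 weeks. The offset per site as the whole cause is argued against by the 64.8% of calls that stayed in the same direction with 1 offset, in a test written beforehand. Spread between animals could raise the calls, since the robust SD of the site statistic was 4.11 at sites with at least 5000 reads and 1.13 at 50 to 200. It cannot be told apart from true differences at many deep sites, because only reads summed over animals are given. In simulated sites a spread of 10% between animals made 58.5% of unchanged deep sites called.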

How the results depend on the processing

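The alternatives with another correlation, rank test, offset, adjustment over all sites, scaled statistic, deep sites, authors' tally, removal of sex-linked genes, age contrasts or input reads were chosen after seeing the data. The design, gene lists, named-gene rule and other alternatives were fixed before the data were examined. In 51 comparisons of a main result with an alternative, 25 stayed within 1.5 times the count or within the spread, and 26 moved. The Apof log2 ratios and the correlations of m6A with RNA kept their sign, but the balance of higher and lower calls turned in places. RNA genes at 28 weeks went from 12 higher and 25 lower to 9 and 7 at 2-fold, and wild-type age sites from 1868 and 454 to 14 and 21. At 8 weeks RNA genes, 377 and 380, became 238 and 207 at 2-fold, and sites, 1420 and 1396, became 829 and 960 at an adjusted p under 0.01, 11 and 149 at 2-fold and 62 and 335 with the scaled statistic; the cause was not tested.

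Requiring an absolute log2 ratio of at least 1 left 445 RNA genes at 8 weeks and 16 at 28 weeks. With age it left 279 in wild type and 437 in knockout. In the same order 160, 39, 35 and 24 m6A sites were left. Fewer features can pass a further condition. At an unadjusted p under 0.05 with an absolute log2 ratio above 1, 215 genes passed at 28 weeks. From summed input reads Apof stood at -0.82 at 8 weeks; the cause was not tested. A preset correlation of 0.05 left 9, 4, 4 and 3 lists in the same order of comparisons, as its wider variance implies. At an adjusted p under 0.01, 1789, 1103 and 1385 m6A sites passed at 8 weeks, 28 weeks and with age in wild type. With the scaled statistic 397, 246 and 223 did. The Spearman rho of m6A with RNA became -0.13, -0.12 and -0.20 with the median over a gene's sites. It became -0.20, -0.039 and -0.24 at sites with at least 1000 reads; the cause was not tested.

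Of 193 tests of named genes, 183 stayed on the same side of the threshold and 10 no longer passed when adjusted over all genes with a p, which tests more genes. These were Nfil3, Cd3g and Cd22 at 8 weeks, Pde7b at 28 weeks, and Kdm5d, Rad51b, Ciart, Cyp4a14, Noct and Alas2 with age in wild type.

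No paired analysis was possible because only sums and comparisons of groups are given, so a replicate block could not be fitted. For the same reason edgeR and DESeq2 refits, other normalizations, a fit of all 12 input libraries, another pseudocount, leaving out a library, splits of the samples, an estimated correlation and fry were not run. A 50% reciprocal overlap of sites was not run because no positions are given.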

Other observations

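All values in this part were looked at only after the results were seen. Xist, the RNA of the inactive X chromosome, had 10192 normalized counts in 8-week knockout and 21017 in 8-week wild type in the authors' deposited table (log2 ratio -1.04 ± 2.15). With age in the knockout the authors' deposited table implied 9451 counts at 28 and 9717 at 8 weeks (-0.04 ± 2.80). The SE of 4 Y-linked genes in the knockout age contrast ran from 2.54 to 3.33, at or above the 99.5 percentile of genes of like level, whose medians were 0.197 to 0.293. Over 5 X-linked genes that escape inactivation the median log2 ratio was -0.25 at 8 weeks and -0.32 with age in wild type, with 0 called by DESeq2.

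Over the genes that decline after birth, 16 of 17 had a positive log2 ratio at 8 weeks and 2 were called, and the median was 0.31 with age in wild type and -0.12 at 28 weeks. Igf2, a fetal growth factor, stood at 2.14 ± 0.74, adjusted p = 0.0683 in the authors' deposited table at 8 weeks. The sheet that holds the 8-week sites is named for week 6.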
